A study of Homo sapiens with 15 samples.

How the data were processed

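RNA bound by exon junction complexes was measured by RIPiT-Seq in HEK293 Flp-In TRex cell lines that stably express FLAG-tagged MAGOH, CASC3 or RNPS1, and RNA-seq was made from rRNA-depleted RNA. Per the labels, RIPiT used an anti-FLAG antibody and then an antibody against EIF4A3, CASC3 or RNPS1. Crosslinked samples were treated with 0.1% formaldehyde for 10 min, and cycloheximide was given at 100 µg/ml for 3 h. Per the submitters' processing notes, adapters were removed with cutadapt 1.16, reads were aligned with TopHat2 2.1.1 to hg38, and bedtools was used afterwards. The deposited tables hold values whose unit is the count, given by the authors as read counts per exon and per transcript for the 15 libraries. They list 279143 exons and 49948 transcripts with 44786 gene symbols, after 19 blank lines were left out. The annotation and the counting settings are not given in the sources used here. Of the transcripts, 43245 were found in GENCODE v29 and held 99.5% of counts, and 99.3% of their exons had the same coordinates there. Transcript values equalled the sum of their exon values in 99.97% of cases. Exons that share their position with another exon made up 2.82%, so some reads may count for more than 1 transcript. Values were whole numbers and were used as deposited.

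Total counts ran from 467741 to 8057700 per library. Counts come from PCR-amplified reads without molecular identifiers in the table, so counting intervals and floors cover counting error only. Libraries were grouped by the tagged protein, the antibody pair, crosslinking and cycloheximide as the labels give them, which made 10 groups, 5 of them native with 1 library each and 5 with 2 libraries. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples. FLAG-CASC3 and FLAG-RNPS1 footprints come from different stable lines. Protein and line therefore cannot be separated in the crosslinked comparisons or in the native pair of CASC3-EIF4A3 and RNPS1-EIF4A3. Counts of CASC3, RNPS1 and MAGOH may include RNA of the transgene.

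Transcript counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test, with TMM scaling, filterByExpr with a minimum count of 10, and a Benjamini-Hochberg adjusted p under 0.05. Fits of the 8 crosslinked libraries gave CASC3 against RNPS1 without and with cycloheximide, the cycloheximide effect in each, and their interaction. Fits of 6 libraries gave CASC3 and RNPS1 footprints against RNA-seq. Comparisons that share a group are not independent. Standard errors are the log2 fold change divided by the square root of the F statistic. A difference between footprints is a difference in shares of a library, not in absolute binding. Exon counts were tested the same way for CASC3 against RNPS1 without cycloheximide, and exon use within genes with diffSpliceDGE and the Simes method. The shares of counts in first, internal, last and single exons were compared with exact two-sided permutation tests in SciPy 1.17.1, 24 in all. Native libraries have no replicates, and log2 CPM ratios with a prior of 2 counts were computed for the transcripts of the crosslinked fit. The median ratio over all these transcripts was subtracted, so 0 marks that median and not equal CPM. Their list medians were set against 10000 random lists matched on expression in 20 bins. Where a group had 1 to 3 counts, the ratio is given with its 95% exact (Clopper-Pearson) counting interval, and at 0 counts a floor of 3 counts over the group was used. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 served for tables and plots.

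The 20 gene lists were fixed before the data were examined: cytoplasmic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrial ribosomal proteins, mitochondrially encoded genes, proteasome, secretory pathway, snoRNA host RNAs, nuclear noncoding RNAs, natural NMD targets, SR and hnRNP genes, detained introns, EJC genes, NMD factors, immediate early genes, heat shock, cell cycle genes (of mitosis and of DNA replication), zinc finger genes, histones and small noncoding RNAs. Lists with at least 5 tested members were tested with camera (limma 3.58.1) with a preset correlation of 0.01, and again with an estimated correlation, with which no list passed in any of the 7 comparisons. Genes were named by a rule also set before the data were examined: the 10 largest changes in each direction among those that passed with an average log2 CPM of at least 4, an official symbol and no overlap between the groups, up to 4 members of each list with the smallest p, and the 5 genes CASC3, RNPS1, EIF4A3, MAGOH and RBM8A. Pseudogene names of the 7SL, 7SK and vault RNA families were left out after the picks were seen. Fewer were printed, in order of rank, and some named by the rule are not reported here.

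Alternatives were DESeq2 size factors in edgeR, no filter, the Wald test of DESeq2 1.42.0, limma-voom for the interaction, multi-exon transcripts only, only the groups compared, a replicate block, and each library left out in turn. Where a group was left with 1 library, that library was assumed to vary like the other groups. For exons and shares, filters of 10 counts were tried, and for native ratios a prior of 0.5 and a minimum of 50 counts. A GC correction, a lowess curve (span 0.3) per library over the GC content of 83.9% of transcripts that hold 93.6% of counts, was added after seeing the data, as were count ratios with 1 library of the higher group left out. The procedure was tested on simulated data with known changes. Mapping of single reads, positions within exons and strand use were not analysed here, and the native MAGOH-EIF4A3 library entered no comparison of CASC3 with RNPS1.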

Results

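Exon junction complexes (EJCs), the protein assemblies that splicing leaves on messenger RNA just upstream of exon junctions, were isolated from HEK293 Flp-In TRex cells, a human embryonic kidney line with a stably integrated FLAG-tagged EJC gene. Each footprint library came from RIPiT, a purification through the FLAG tag of 1 EJC protein followed by an antibody against another, and RNA protected from RNase I was sequenced. EIF4A3, MAGOH and RBM8A are core proteins of the complex, while CASC3 and RNPS1 are peripheral proteins. The 15 libraries formed 10 groups. Native (not crosslinked) footprints held 5 protein pairs with 1 library each, namely MAGOH-EIF4A3, CASC3-EIF4A3, RNPS1-EIF4A3, MAGOH-CASC3 and MAGOH-RNPS1. Formaldehyde-crosslinked footprints of CASC3-EIF4A3 and RNPS1-EIF4A3, without or with cycloheximide, an inhibitor of translation elongation, made 4 groups of 2 libraries. A further 2 libraries held RNA-seq of rRNA-depleted RNA.

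Total transcript counts of the native libraries were 4503784 for MAGOH-EIF4A3, 935667 for CASC3-EIF4A3, 2232968 for RNPS1-EIF4A3, 1521092 for MAGOH-CASC3 and 3135860 for MAGOH-RNPS1. Crosslinked CASC3 libraries held 943925 and 794010 counts, and crosslinked RNPS1 libraries 2351986 and 4143750. With cycloheximide the totals were 8057700 and 6701629 for CASC3 and 7251722 and 467741 for RNPS1. RNA-seq libraries held 1145581 and 1183520. Replicate log2 CPM (counts scaled to library size) correlated across transcripts with r = 0.908 for crosslinked CASC3, 0.952 for crosslinked RNPS1, 0.971 for treated CASC3, 0.772 for treated RNPS1 and 0.961 for RNA-seq. Transcripts are not independent replicates. The count-weighted mean GC content was 47.3% and 48.2% in the treated CASC3 libraries, 48.3% and 52.8% in the treated RNPS1 libraries, and between 51.9% and 54.2% in the untreated crosslinked libraries.

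Without cycloheximide, CASC3 and RNPS1 footprints were compared to ask which transcripts carry relatively more of either form of the EJC. Transcripts of cytoplasmic ribosomal proteins took a larger share of the CASC3 libraries. RPS12 (ENST00000230050, a small-subunit protein gene with 6 exons on chromosome 6, 132814441 to 132817564, hg38) was higher in CASC3 by a log2 fold change of 5.96 ± 0.70 (SE, n = 2 per group, edgeR adjusted p = 0.0032), with 946 and 2960 CPM against 32.7 and 40.1. RPS18 was higher by 4.89 ± 0.67, with 997 and 3110 CPM against 92.7 and 71.4. MRPS24 (ENST00000317534, chromosome 7, 43866558 to 43869557), which encodes a protein of the mitochondrial ribosome, was higher by 5.98 ± 0.67 (adjusted p = 0.0032). OTUB1 (ENST00000538426, chromosome 11, 63986413 to 63998415), a deubiquitinase gene, was the only transcript lower in CASC3, at -2.12 ± 0.44 (adjusted p = 0.047), with 44.5 and 30.2 CPM against 156 and 199, and it did not pass with DESeq2 size factors (adjusted p = 0.0502).

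Across the 83 tested ribosomal protein transcripts the median log2 difference was 1.76 and all 83 values were positive, against -0.09 for all 14297 transcripts. Of these, 17 were called higher, 0 lower and 66 were not called, and adjusted over the list alone 62 were higher. The list test gave an adjusted p of 1.98e-56, and an adjusted p = 0.154 with an estimated correlation. RPL39 (5.0 ± 0.87), RPL35 (4.50 ± 0.86), RPL18 (4.28 ± 0.76) and RPS27 (4.01 ± 0.58) were among those called. Reads of these short genes can be shared with many near-identical processed pseudogenes, so their counts are less certain than others. Translation factor transcripts, which like ribosomal protein transcripts often start with a terminal oligopyrimidine tract, had a median of 0.26 with 2 higher and 36 not called (8 higher adjusted over the list alone, list adjusted p = 0.000262, adjusted p = 0.313 with an estimated correlation). FAU, which encodes a ribosomal protein fused to a ubiquitin-like domain, was higher by 3.05 ± 0.52 and NACA, a subunit of the nascent polypeptide-associated complex, by 2.89 ± 0.58. Without crosslinked CASC3 replicate 1 the median of the translation factors was 0.14, and without crosslinked RNPS1 replicate 1 it was 0.41.

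TMA7, a translation machinery gene, was higher in CASC3 by 4.78 ± 0.78, RPS19BP1, whose product binds RPS19, by 4.75 ± 0.61 and COMMD6 by 4.54 ± 0.60. URGCP-MRPS24, a readthrough transcript that shares exons with MRPS24, was higher by 4.68 ± 0.57. Among 73 mitochondrial ribosomal protein transcripts 4 were higher and 69 not called, including MRPS36 (4.68 ± 0.75) and MRPL57 (2.83 ± 0.53). Adjusted over the list alone, 13 were higher and 1 lower. This list had a median of -0.11, a mean of 0.24 and an upward test that did not pass (adjusted p = 0.135). Of 22 snoRNA host RNAs 2 were higher, SNHG5 (3.32 ± 0.67) and EPB41L4A-AS1 (3.15 ± 0.66), and 20 were not called. Their list median was 0.36 (2 higher adjusted over the list alone, adjusted p = 0.00488, adjusted p = 0.393 with an estimated correlation). Without crosslinked RNPS1 replicate 1 this list did not pass (0.0873, median 0.11), and its median was 0.59 without crosslinked CASC3 replicate 1, 0.13 without CASC3 replicate 2 and 0.77 without RNPS1 replicate 2. ZNF865 (3.38 ± 0.59) and ZNF446 (2.28 ± 0.46) were among 3 of 438 zinc finger transcripts called higher.

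Intronless replication-dependent histone transcripts had a median of 0.97 with 36 of 37 values positive, 0 called over all transcripts and 9 higher adjusted over the list alone. Their list test passed (adjusted p = 7.03e-11, adjusted p = 0.313 with an estimated correlation), and the median was 1.70 without crosslinked RNPS1 replicate 1. HIST1H4B stood at 2.65 ± 0.63 (adjusted p = 0.089). Small noncoding RNAs had a median of 1.60, 2 of 28 higher, RN7SL2 (4.10 ± 0.72) and RN7SL1 (3.90 ± 0.75), both RNAs of the signal recognition particle, and 26 not called (9 higher adjusted over the list alone, list adjusted p = 2.22e-07, adjusted p = 0.393 with an estimated correlation). This rested on crosslinked CASC3 replicate 2, without which the median was -0.86 and the adjusted p 0.357, while it was 2.5 without replicate 1. Nuclear-encoded oxidative phosphorylation transcripts had a median of 0.44 with 0 of 80 called over all or adjusted over the list alone (list adjusted p = 0.00653, adjusted p = 0.393 with an estimated correlation), and 0.29 without crosslinked CASC3 replicate 2.

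Lists that lay lower in CASC3 were transcripts with detained introns and those of splicing factors. The 15 detained-intron transcripts had a median of -0.86 with 1 positive value, 0 called over all transcripts and 3 lower adjusted over the list alone (list adjusted p = 0.000197, adjusted p = 0.154 with an estimated correlation). POLG2 stood at -1.55 ± 0.48 and ANKRD10 at -1.30 ± 0.42. SR and hnRNP protein transcripts, many of which contain poison exons, had a median of -0.43 with 8 of 40 values positive and 0 called over all or adjusted over the list alone (list adjusted p = 0.0031, adjusted p = 0.313 with an estimated correlation). Their median was -0.66 without crosslinked CASC3 replicate 2 and -0.28 without RNPS1 replicate 2. SRSF5 stood at -1.38 ± 0.47. The other lists did not pass, with medians of -0.15 for the proteasome, 0.06 for secretory pathway genes, 0.05 for nuclear noncoding RNAs, 0.25 for natural targets of nonsense-mediated decay (NMD), -0.09 for EJC genes, 0.13 for NMD factors, 0.09 for immediate early genes, 0.15 for heat shock genes, -0.08 for cell cycle genes and -0.08 for zinc finger genes (adjusted p from 0.202 to 0.994). Of these, 1 heat shock transcript and 4 zinc finger transcripts were higher adjusted over the list alone. The list of mitochondrially encoded genes had 0 tested members. CASC3 (0.19 ± 0.45), EIF4A3 (0.17 ± 0.47), MAGOH (0.80 ± 0.69), RBM8A (-0.33 ± 0.47) and RNPS1 (1.57 ± 0.58) were not called, and counts of tagged genes can include transgene RNA.

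In this comparison 79 transcripts were higher and 1 lower of 14297 (edgeR, 1638 at an unadjusted p under 0.05). The count depended on single libraries of the compared groups. It also depended on the treated libraries, which enter this contrast only through the shared spread, scaling and filter. There were 2 called without crosslinked CASC3 replicate 2, 0 without crosslinked RNPS1 replicate 1 (965 unadjusted) or 2 (772 unadjusted), 11 without either treated CASC3 library, and 699 (511 higher, 188 lower) and 795 (592 higher, 203 lower) without treated RNPS1 replicates 1 and 2. DESeq2 called 266 transcripts (8 lower), a GC correction chosen after seeing the data gave 318 (20 lower), and a fit of the 4 libraries of these groups alone called 612 (494 higher, 118 lower). The split between higher and lower depended on the setting. Of the 22 named transcripts that passed, 3 were lost without crosslinked CASC3 replicate 1, 20 without replicate 2, all 22 without either crosslinked RNPS1 library and 15 without either treated CASC3 library.

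**Figure D1:**
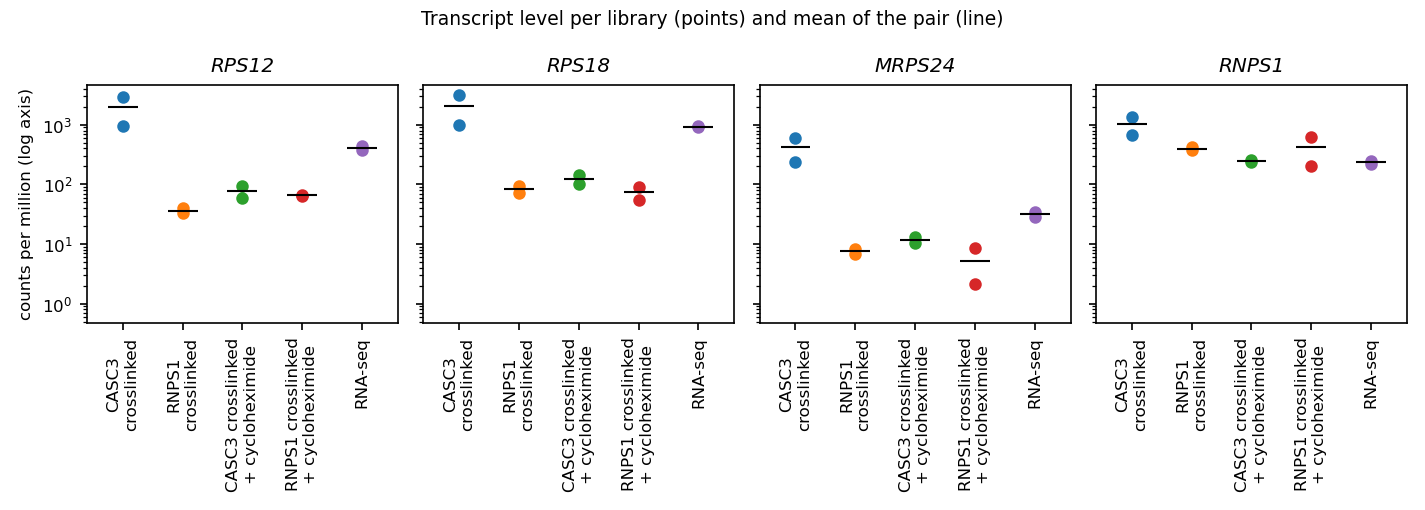
CPM, library-scaled counts (log axis), of RPS12, RPS18, MRPS24 and RNPS1 in each library of the 5 replicated groups, with points for libraries and a line at the mean of each pair. RPS12 stands at 946 and 2960 in crosslinked CASC3 footprints and at 32.7 and 40.1 in crosslinked RNPS1 footprints.

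At the level of exons, 299 were higher in CASC3 and 0 lower of 104449 tested (edgeR, 7661 at an unadjusted p under 0.05). Called exons comprised 79 of 8557 first exons, 197 of 83988 internal exons, 8 of 10722 last exons and 15 of 621 exons of single-exon transcripts. The exon with the smallest p was exon 1 of RPS12 (chromosome 6, 132814441 to 132814613, GC content 64.7%), at 7.67 ± 1.02 (adjusted p = 6.34e-09). Exon 1 of MRPS24 was also higher, by 7.63. These exons were chosen after their values were seen. Use of exons within a gene differed in 0 of 10717 genes (edgeR diffSpliceDGE, 229 at an unadjusted p under 0.05). Without crosslinked CASC3 replicate 2, 5 exons were called, and without crosslinked RNPS1 replicate 1 or 2 there were 0 (3895 and 3090 unadjusted). Without treated CASC3 replicates 115 and 113 were called. Without treated RNPS1 replicates there were 3439 (2712 higher, 727 lower) and 3148 (2447 higher, 701 lower), and exon use was then called in 31 and 21 genes. With only exons averaging at least 10 counts in every group, 0 of 16719 were called (1570 unadjusted), and the GC correction gave 935 exons (14 lower) and 1 gene.

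Native footprints, from single libraries with no replicates, gave another view of the CASC3 to RNPS1 difference. Log2 ratios were centred on the median of all transcripts of each pair. Ribosomal protein transcripts were on the CASC3 side in both protein pairs: the median log2 ratio was 0.45 for CASC3-EIF4A3 over RNPS1-EIF4A3, with 75 of 83 above 0, and 0.27 for MAGOH-CASC3 over MAGOH-RNPS1, with 73 of 83 above 0. Both exceeded all 10000 random lists of matched expression, whose 95% ranges were -0.04 to 0.18 and -0.04 to 0.08. Log2 ratios were 2.5 and 1.47 for RPS12, 1.08 and 0.59 for RPS18, 3.09 and 2.02 for MRPS24, and -0.99 and -0.06 for OTUB1. Of the 79 transcripts called higher in crosslinked CASC3 footprints, 77 were above 0 in the EIF4A3 pair (median 1.04) and 70 in the MAGOH pair (median 0.51). The MAGOH-CASC3 and MAGOH-RNPS1 libraries were both made from FLAG-MAGOH cells. The EIF4A3 pair came from the FLAG-CASC3 and FLAG-RNPS1 lines, as the crosslinked libraries did, so protein and line cannot be separated in it.

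In both native pairs heat shock transcripts, with medians of 0.34 and 0.27, and translation factors, with 0.27 and 0.14, lay above 99% of random lists. SR and hnRNP transcripts had -0.27 in the EIF4A3 pair, below all random lists, and 0.05 in the MAGOH pair (percentile 80.3), and detained-intron transcripts -0.40 (percentile 0.07) and 0.02 (percentile 52.4). Across 14297 transcripts, which are not independent replicates, the ratios of the native pairs correlated with Pearson r = 0.172 and Spearman rho = 0.190. The correlation with the crosslinked log2 fold change was 0.429 (rho 0.457) for the EIF4A3 pair and 0.175 (rho 0.178) for the MAGOH pair. Over the 4421 transcripts with at least 50 counts in each native library the Pearson values were 0.389, 0.672 and 0.361.

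With cycloheximide, the same comparison called more transcripts in the fit of all crosslinked libraries (2017 against 80). This turned around in fits of the compared groups alone, with 0 called against 612 without cycloheximide, and without either treated CASC3 library, with 0 against 11. Cell cycle genes were higher in CASC3 footprints with a median of 1.58 (16 of 33 higher, 0 lower, 17 not called), including KIF20A, a mitotic kinesin (2.65 ± 0.50), CCNA2, cyclin A2 (2.26 ± 0.42), and RRM1, a subunit of ribonucleotide reductase (2.34). Proteasome transcripts had a median of 1.09 (12 of 34 higher, 0 lower), with PSMC1 at 1.99 ± 0.45 and PSMD12 at 1.84, and heat shock transcripts a median of 1.57 (11 of 22 higher, 0 lower), with the chaperones HSPA8 at 2.83 ± 0.48 and HSPH1 at 2.21, and the chaperonin subunit CCT6A at 1.86. On the RNPS1 side stood nuclear noncoding RNAs, with a median of -2.28 (7 of 11 lower, 0 higher), among them MIAT (-4.75 ± 0.86), FTX (-2.75 ± 0.59), NEAT1, the scaffold of paraspeckles (-2.64 ± 0.66), and KCNQ1OT1 (-2.28). EIF4A3 itself was higher in CASC3 by 3.08 ± 0.49 (n = 2 per group, edgeR adjusted p = 0.0089), with 226 and 286 CPM against 49.5 and 23.5.

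Adjusted over the list alone, 22 cell cycle, 14 proteasome and 13 heat shock transcripts were higher and 8 nuclear noncoding RNAs lower. List tests gave adjusted p of 2.08e-10, 2.67e-07, 2.57e-07 and 0.000475, and with an estimated correlation adjusted p = 0.116, adjusted p = 0.116, adjusted p = 0.116 and adjusted p = 0.216. Translation factors had a median of 1.23 (9 higher, 2 lower, 27 not called, and 21 higher and 2 lower adjusted over the list alone, adjusted p = 5.55e-06), with EIF4G2 at 2.29 ± 0.48 and EEF1D at -2.32 ± 0.57, and secretory pathway transcripts 0.74 (6 higher of 59, 5 adjusted over the list alone, adjusted p = 7.39e-05), with RPN1, an oligosaccharyltransferase subunit, at 2.08 ± 0.44. Both had an adjusted p = 0.116 with an estimated correlation. Immediate early genes had a median of 1.21 and a mean of 0.80 (8 higher, 1 lower of 38, and 14 higher and 1 lower adjusted over the list alone, adjusted p = 0.0147, adjusted p = 0.689 with an estimated correlation), with DUSP1 at 2.55 ± 0.48 and BTG1 at 2.36. Natural NMD targets had 0.45 (2 higher of 27, 2 adjusted over the list alone, adjusted p = 0.0174, adjusted p = 0.39 with an estimated correlation), with the stress gene SESN2 at 2.06 ± 0.52.

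Zinc finger transcripts had a median of -0.62 (7 higher and 50 lower of 438, and 5 higher and 42 lower adjusted over the list alone, adjusted p = 0.000526), with ZNF83 at -3.14 ± 0.53, ZNF334 at -2.64 and ZNF217 at 2.37 ± 0.46. Histone transcripts had a median of -1.21 (4 lower of 37, 4 adjusted over the list alone, adjusted p = 4.77e-05), with HIST1H1C at -3.53 ± 0.78 and HIST1H1D at -3.10 ± 0.69. Both had an adjusted p = 0.39 with an estimated correlation. The remaining lists did not pass, with medians of 0.13 for ribosomal proteins (3 higher, 3 lower, and 1 higher adjusted over the list alone), -0.04 for oxidative phosphorylation, 0.24 for mitochondrial ribosomal proteins, 0.12 for snoRNA hosts (mean -0.18), 0.48 for SR and hnRNP genes, -0.66 for detained introns, 0.41 for EJC genes, 0.19 for NMD factors and -1.43 for small RNAs (adjusted p from 0.0517 to 0.939). Without treated RNPS1 replicate 1 the calls of nuclear noncoding RNAs (adjusted p 0.171, median -0.96), NMD targets (0.422), immediate early genes (0.962, with the test pointing down) and zinc fingers (0.0716, median -0.01) were lost, and those of NMD targets (0.0903, median 0.29) and immediate early genes (0.191, median 0.38) also without treated CASC3 replicate 2. Other medians moved by over 1.5 times without treated RNPS1 replicate 1 (proteasome 1.79, secretory 1.25) or replicate 2 (histones -0.74, NMD targets 1.04) and with the GC correction (NMD targets 0.72).

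Among the largest single changes were higher levels over SPATA5L1 (3.29 ± 0.45), the phosphatase PTP4A1 (3.25 ± 0.53), NFKBIA, the inhibitor of NF-kB (3.19 ± 0.52), and ARC (3.18 ± 0.85). The microRNA hairpins MIR17 (4.27 ± 0.80), MIR20A (4.09), MIR15A (3.65), MIR19A (3.27), MIR196B (3.24) and MIR423 (3.20) were also higher, although they lie inside longer host transcripts and MIR423 did not pass in DESeq2 (adjusted p = 0.101). Lower in CASC3 were SLC25A29, a mitochondrial carrier (-4.93 ± 0.62), the homeobox genes HOXD9 (-4.60 ± 0.58) and NKX2-1 (-4.48), RAB26 (-5.08 ± 0.94), LINC00202-1 (-5.04), TNFRSF13C (-4.23 ± 0.53), SKIDA1 (-4.14) and KIFC2 (-4.13 ± 0.73). DUX4, a multi-copy gene, stood at -5.64 ± 1.15. RELN had 3 counts in the treated CASC3 libraries and 5 and 20 in treated RNPS1 replicates 1 and 2. Its pooled ratio, 15.9-fold higher in RNPS1 (95% counting interval 4.86 to 82.4), was 210 without treated RNPS1 replicate 1 and 3.39 without replicate 2, so its size rests on single libraries. PNN, a splicing factor that binds RNPS1, was lower by -2.76 ± 0.48, and CASC3 (0.01) and RNPS1 (-0.41) were not called.

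With cycloheximide 918 transcripts were higher in CASC3 and 1099 lower of 14297 (edgeR, 4825 unadjusted). The count was 1223 and 1248 without untreated CASC3 replicates 1 and 2, 1166 and 1087 without untreated RNPS1 replicates, 0 without either treated CASC3 library (3284 and 3019 unadjusted), and 5011 (2895 higher, 2116 lower) and 3132 (1722 higher, 1410 lower) without treated RNPS1 replicates 1 and 2. A fit of these 4 libraries alone called 0 (3404 unadjusted), while DESeq2 called 2576. Of 45 named transcripts that passed, ARC, FTX and NEAT1 were lost without treated RNPS1 replicate 1, and EEF1D and RELN without replicate 2. Mean GC content was 47.3% and 48.2% in the treated CASC3 libraries and 48.3% and 52.8% in the treated RNPS1 libraries.

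Within CASC3 footprints, cycloheximide was compared with no treatment to see how footprint shares change when translation is blocked. The RNA-seq libraries had no cycloheximide, so changes in footprints of either complex cannot be told apart from changes in RNA level. Among transcripts that gained footprints were ARRDC3, an arrestin-domain gene (4.74 ± 0.60, edgeR adjusted p = 0.0011, n = 2 per group), TIPARP (4.57 ± 0.75) and the inhibitors of DNA binding ID3 (4.31 ± 0.66) and ID1 (3.94 ± 0.58), the latter from 4.24 and 3.78 to 55.4 and 51.6 CPM. The signal recognition particle RNA RN7SL1 fell by 7.30 on the log2 scale (SE 0.88), from 454 and 2090 to 6.83 and 8.06 CPM, and RPPH1, the RNA of RNase P, fell by 6.73 (SE 1.02). Ribosomal protein transcripts fell with a median of -1.04 (4 higher, 33 lower, 46 not called of 83), with RPS12 at -4.58 ± 0.65, RPL35 at -4.99 ± 0.88, RPS18 at -3.94 and RPS27 at -3.55. EIF4A3 rose by 2.54 ± 0.48 and RNPS1 fell by 1.91 (SE 0.59, adjusted p = 0.026).

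Adjusted over the list alone, 5 ribosomal protein transcripts were higher and 37 lower (list adjusted p = 3.63e-05, adjusted p = 0.501 with an estimated correlation). Without untreated CASC3 replicate 2 their median was -0.48. Small RNAs had a median of -3.84 (17 of 28 lower, 18 adjusted over the list alone, adjusted p = 6.87e-08), including RN7SL2 (-6.62 ± 0.82) and RMRP (-5.13 ± 0.63). Their median was -2.04 without untreated CASC3 replicate 2 and -5.77 without treated CASC3 replicate 1. SnoRNA hosts had -0.96 (7 of 22 lower, 8 adjusted over the list alone, adjusted p = 0.00969), including SNHG4 (-5.21 ± 0.73) and SNHG7 (-2.47), the latter not called with the GC correction (-0.60, adjusted p 0.248). Nuclear noncoding RNAs had -1.49 (5 of 11 lower, 5 adjusted over the list alone, adjusted p = 0.00487, and a median of -2.28 without treated CASC3 replicate 1), including NEAT1 (-4.32 ± 0.71) and MALAT1 (-3.45 ± 0.69). The last 3 lists had an adjusted p = 0.37 with an estimated correlation.

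Proteasome transcripts rose with a median of 1.54 (18 of 34 higher, 21 adjusted over the list alone, adjusted p = 8.4e-07), among them PSMD6 (2.62 ± 0.45) and PSMD12 (2.57). Cell cycle transcripts rose with a median of 1.49 (21 of 33, 21 adjusted over the list alone, adjusted p = 9.99e-07), among them CCNA2 (2.97 ± 0.45) and RRM1 (2.98). Heat shock transcripts rose with a median of 1.73 (13 higher, 1 lower of 22, and 14 higher and 1 lower adjusted over the list alone, adjusted p = 3.19e-05), with CCT6A at 2.74 ± 0.43, HSPA4 at 2.76 and HSPA1B, an intronless gene, at -3.94 ± 0.64. Translation factors had 1.02 (15 higher, 5 lower of 38, and 16 higher and 6 lower adjusted over the list alone, adjusted p = 0.00969), with EIF4G2 at 2.86 ± 0.49 and FAU at -3.21 ± 0.52. Secretory transcripts had 0.72 (9 higher, 3 lower of 59, the same counts adjusted over the list alone, adjusted p = 0.0168), with RPN1 at 2.00 ± 0.44 and ERGIC1 at -2.94 ± 0.53. SR and hnRNP transcripts had 0.92 (11 higher, 2 lower of 40, the same counts adjusted over the list alone, adjusted p = 0.00969), with TRA2B at 1.98 ± 0.43 and SON at 2.38 ± 0.56. All 6 lists had an adjusted p = 0.37 with an estimated correlation. With the GC correction the median of SR and hnRNP transcripts was 0.12 (adjusted p 0.476), that of translation factors 0.46, cell cycle genes 0.96, heat shock genes 1.05 and secretory genes 0.47. Without untreated CASC3 replicate 1 translation factors did not pass (0.0985).

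Immediate early genes had a median of 1.19 (16 higher, 3 lower of 38, and 17 higher and 6 lower adjusted over the list alone, adjusted p = 0.0149, adjusted p = 0.501 with an estimated correlation), with KLF10 at 3.35 ± 0.54 and ID2 at 3.14 ± 0.48. Without treated CASC3 replicate 2 this list did not pass (0.193, median 0.44). Lists that did not pass had medians of -0.14 for oxidative phosphorylation, 0.18 for mitochondrial ribosomal proteins (19 higher, 13 lower), 0.30 for NMD targets, 0.27 for detained introns (4 higher), 0.51 for EJC genes, 0.68 for NMD factors, 0.05 for zinc fingers (mean -0.11, 32 higher, 51 lower) and -0.35 for histones (3 lower), with adjusted p from 0.13 to 0.733. Within them MRPS24 fell by 5.03 (SE 0.63), CCNL1, a cyclin of the splicing machinery with a detained intron, rose by 2.56 ± 0.48, and SMG8, a regulator of the NMD kinase SMG1, rose by 3.29 ± 0.52.

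Further transcripts that rose were TRMT6, a tRNA methyltransferase subunit (4.23 ± 0.58), DNTTIP2 (3.90 ± 0.52), NUFIP1 (3.89), STK17B (3.81) and NOL11, a factor of ribosome biogenesis (3.81 ± 0.75), and ZNF654 had 3 counts without treatment and was 32.1-fold higher with it (95% counting interval 10.9 to 156). Further transcripts that fell were METRN (-6.08 ± 0.89), HIC1 (-6.03 ± 1.33), MDK, which encodes the growth factor midkine (-5.67 ± 1.00), NKX2-1 (-5.48 ± 0.83) and the multi-copy sequences DUX4 (-6.94 ± 1.20) and MTRNR2L8 (-6.46 ± 1.11). RELN had 3 counts with treatment and was 1230-fold higher without it (95% counting interval 420 to 6010). RBM8A rose by 1.40 ± 0.47 (adjusted p = 0.037), which did not pass with the GC correction (0.61, adjusted p 0.35), and CASC3 stood at 0.39 ± 0.45. In all, 2293 transcripts rose and 2258 fell of 14297 (edgeR, 6343 unadjusted). The count was 2174 (876 higher, 1298 lower) and 356 (64 higher, 292 lower) without untreated CASC3 replicates 1 and 2, 1271 (760 higher, 511 lower) and 1098 without treated CASC3 replicates 1 and 2. It was 6897 and 7030 without treated RNPS1 replicates 1 and 2. Of 50 named transcripts that passed, 18 were lost without untreated CASC3 replicate 2, namely CCNL1, EIF4A3, EIF4G2, ERGIC1, HIC1, HSPA4, MALAT1, MTRNR2L8, NOL11, PSMD12, RBM8A, RNPS1, RPN1, RRM1, SNHG7, SON, STK17B and TRA2B. RBM8A was also lost without any other CASC3 library or either untreated RNPS1 library, HIC1 and RNPS1 without either treated CASC3 library, SNHG7 without treated CASC3 replicate 1, RPN1 and SON without replicate 2, and TRA2B without untreated CASC3 replicate 1 or treated CASC3 replicate 2. Mean GC content was 52.9% and 54.2% without and 47.3% and 48.2% with treatment. The GC correction called 3124 transcripts, of which 2122 were among the 4551 called without it. Scaling with DESeq2 size factors moved the median of all transcripts from 0.06 to -0.05.

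**Figure D2:**
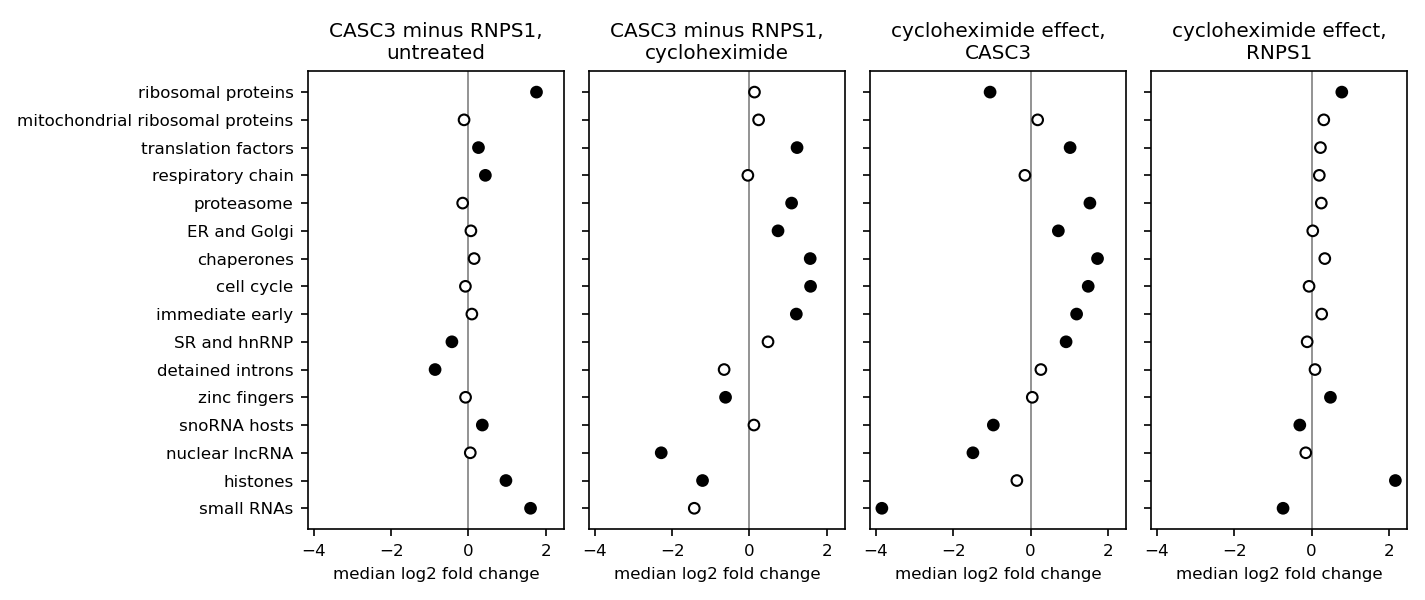
Median log2 fold change of 16 gene lists in the comparisons of CASC3 with RNPS1, without and with cycloheximide, and in the cycloheximide effect of each. Filled points passed the list test with its preset correlation at an adjusted p under 0.05 and open points did not.

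Within RNPS1 footprints, the same treatment gave 0 transcripts that rose and 3 that fell of 14297 (edgeR, 1890 unadjusted). SLC6A9, a glycine transporter gene (chromosome 1, 43996483 to 44031386), fell by 3.90 on the log2 scale (SE 0.53, n = 2 per group, adjusted p = 0.024), from 137 and 95.6 to 6.62 and 10.7 CPM. RAPGEF3, an exchange factor activated by cyclic AMP (chromosome 12, 47737246 to 47771034), fell by 3.44 (SE 0.52, adjusted p = 0.042), from 111 and 146 to 9.65 and 17.1 CPM. AC003001.1, a clone-named single-exon transcript (chromosome X, 85244095 to 85244171) named after its values were seen, fell by 5.94 (SE 0.82, adjusted p = 0.024). RAPGEF3 did not pass among multi-exon transcripts only (adjusted p = 0.0567), where 1 transcript was called. The count was 0 without either untreated CASC3 library (1711 and 1690 unadjusted), 2 without untreated RNPS1 replicate 1, 0 without replicate 2 (396 unadjusted), 0 without either treated CASC3 library (1526 and 1516 unadjusted), and 672 (317 higher, 355 lower) and 2033 (876 higher, 1157 lower) without treated RNPS1 replicates 1 and 2. A fit of these 4 libraries alone called 0 (951 unadjusted), DESeq2 called 126 (54 higher, 72 lower) and the GC correction gave 21 (15 higher, 6 lower).

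Histone transcripts shifted upward with treatment in RNPS1 footprints, with a median of 2.17 and 35 of 37 values positive. Of these 0 were called over all transcripts and 25 were higher adjusted over the list alone (list adjusted p = 2.34e-27, adjusted p = 0.266 with an estimated correlation), with HIST1H1D at 4.67 ± 0.79 and HIST1H4B at 3.47 ± 0.61. Ribosomal protein transcripts had a median of 0.78 with 69 of 83 positive, 0 called and 13 higher adjusted over the list alone (list adjusted p = 2.08e-10), including RPS27A (2.09 ± 0.44) and RPS23 (3.01 ± 0.73). Zinc finger transcripts had 0.49 with 336 of 438 positive and 0 called over all or adjusted over the list alone (list adjusted p = 5.14e-06, median 0.16 without treated RNPS1 replicate 1). Small RNAs had -0.74 with 0 called and 1 lower adjusted over the list alone (list adjusted p = 0.000496), and snoRNA hosts -0.30 with 0 called over all or adjusted over the list alone (list adjusted p = 0.0377). These 4 lists had an adjusted p = 0.663 with an estimated correlation.

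Without treated RNPS1 replicate 2 neither small RNAs (0.464) nor snoRNA hosts (0.492, median -0.18) passed, and snoRNA hosts also did not pass without untreated RNPS1 replicate 2 (0.101, median -0.18). The small RNA median was -6.14 without treated RNPS1 replicate 1, -1.23 without replicate 2, -0.46 with the GC correction, and -1.36 and -1.39 without treated CASC3 replicates 1 and 2. The snoRNA host median was -0.47 without untreated RNPS1 replicate 1 and -0.90 without treated RNPS1 replicate 1. Immediate early genes had a median of 0.26 with 2 of 38 higher adjusted over the list alone (list adjusted p = 0.0759), with ID1 at 2.33 ± 0.50 and ID3 at 2.45 ± 0.56. Cell cycle genes had -0.06 with 2 lower adjusted over the list alone, including PLK1 (-1.76 ± 0.44) and AURKB (-2.14 ± 0.55), and NMD targets -0.25 with 3 lower adjusted over the list alone, including CARS (-1.74 ± 0.43) and the cystine transporter SLC7A11 (-2.24 ± 0.57). The other lists had medians from -0.15 (nuclear noncoding RNAs) to 0.57 (NMD factors) and did not pass (adjusted p from 0.102 to 0.995), and detained introns had a median of 0.09 and a mean of -0.01 (log2). EIF4A3 (-0.37), RNPS1 (0.07) and CASC3 (0.57) were not called.

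The interaction asked whether cycloheximide acted differently on CASC3 and RNPS1 footprints. No transcript passed, with 0 of 14297 called in edgeR (2506 at an unadjusted p under 0.05, smallest adjusted p 0.0664) and 0 in limma-voom (2485 unadjusted), but 390 in DESeq2. RPS12 (-5.41 ± 0.86), RPL35 (-7.08 ± 1.17), RPL29 (-4.86 ± 0.85), FAU (-4.18 ± 0.72), MRPS24 (-4.89 ± 0.86), ZNF865 (-5.20 ± 0.87) and RMRP (-4.08 ± 0.78) all stood at an adjusted p of 0.066. CCNA2 stood at 2.78 ± 0.60, EIF4A3 at 2.90 ± 0.67, HSPA8 at 2.66 ± 0.65, PSMD6 at 2.34 ± 0.60 and NEAT1 at -4.11 ± 0.92. Without untreated CASC3 replicate 1, 37 transcripts were called, and without treated RNPS1 replicates 1 and 2, 3474 and 502. The other replicates left out gave 0, and the fit without a count filter called 459 and the GC correction 230.

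By lists, the change with cycloheximide in CASC3 minus that in RNPS1 was negative for histones (median -2.60, 0 of 37 values positive, 20 lower adjusted over the list alone, adjusted p = 1.05e-15, adjusted p = 0.19 with an estimated correlation) and ribosomal proteins (-1.77, 9 of 83 positive, 38 lower adjusted over the list alone, adjusted p = 2.71e-19, adjusted p = 0.197 with an estimated correlation). It was also negative for small RNAs (-2.92, 10 lower adjusted over the list alone, adjusted p = 3.09e-06, adjusted p = 0.357 with an estimated correlation), nuclear noncoding RNAs (-1.33, 4 lower adjusted over the list alone, adjusted p = 0.000985, adjusted p = 0.197 with an estimated correlation) and zinc fingers (-0.49, 8 lower adjusted over the list alone, adjusted p = 0.00147, adjusted p = 0.357 with an estimated correlation). It was positive for cell cycle genes (1.52, 32 of 33 positive, 13 higher adjusted over the list alone, adjusted p = 1.68e-11) and proteasome genes (1.21, 0 called adjusted over the list alone, adjusted p = 1.25e-07), both with an adjusted p = 0.173 with an estimated correlation. Heat shock genes had 1.49 (4 higher, 1 lower adjusted over the list alone, adjusted p = 3.42e-05, adjusted p = 0.197 with an estimated correlation), SR and hnRNP genes 0.93 (0 adjusted over the list alone, adjusted p = 0.000179, adjusted p = 0.19 with an estimated correlation) and secretory genes 0.66 (0 adjusted over the list alone, adjusted p = 0.0059, adjusted p = 0.261 with an estimated correlation). Without treated RNPS1 replicate 1 nuclear noncoding RNAs (0.167), zinc fingers (0.0665, median 0.16) and small RNAs (0.964, median 0.83) did not pass. The other lists did not pass (adjusted p from 0.0684 to 0.847), with medians of 0.72 for translation factors, -0.32 for oxidative phosphorylation, 0.10 for mitochondrial ribosomal proteins (mean -0.14), -0.92 for snoRNA hosts, 0.43 for NMD targets, 0.04 for detained introns, -0.07 for EJC genes (mean 0.22), 0.39 for NMD factors and 0.98 for immediate early genes. Other medians moved by over 1.5 times without treated RNPS1 replicate 1 (heat shock 2.26, secretory 1.17, SR and hnRNP 1.52), without treated CASC3 replicate 1 (nuclear noncoding RNAs -2.70), without untreated CASC3 replicate 2 (small RNAs -1.32) and with the GC correction (heat shock 0.95, SR and hnRNP 0.49, secretory 0.20, zinc fingers -0.83).

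Crosslinked CASC3 footprints were compared with RNA-seq to ask which transcripts have a larger share of footprint counts than of RNA-seq counts. Transcripts that lack exon junctions served as background. Counts were not adjusted for transcript length or number of junctions, so differences can also reflect these. Intronless histone transcripts were lower in footprints with a median of -2.75 (39 of 40 lower, 0 higher, and 39 adjusted over the list alone), with HIST1H2AG at -4.27 ± 0.34 and HIST1H2AI at -4.44. Small RNAs had a median of -3.16 (21 of 28 lower, 22 adjusted over the list alone), with the Y RNAs RNY1 at -6.79 ± 0.64, RNY4 at -6.25 ± 0.80 and RNY3 at -5.88 ± 0.68 (n = 2 per group, edgeR). Higher than in RNA-seq were SR and hnRNP transcripts, with a median of 0.75 (20 higher, 2 lower of 40, the same counts adjusted over the list alone), including LUC7L (2.35), and detained-intron transcripts, with 1.06 (9 of 15 higher, 10 adjusted over the list alone), including the kinase CLK2 (2.24 ± 0.31) and PABPN1 (2.44). Adjusted p of these 4 lists were 2.53e-17, 4.4e-13, 0.00307 and 0.00368, each with an adjusted p = 0.204 with an estimated correlation. The small RNA median was -1.53 and -5.06 without CASC3 replicates 1 and 2 and -1.96 without RNA-seq replicate 1, and that of SR and hnRNP transcripts 0.47 without CASC3 replicate 1 and 1.23 with the GC correction.

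Ribosomal protein transcripts were lower in CASC3 footprints than in RNA-seq, with a median of -1.09 (4 higher, 46 lower of 82, the same counts adjusted over the list alone, adjusted p = 4.52e-10, adjusted p = 0.374 with an estimated correlation) and -1.65 without CASC3 replicate 2, among them RPS3A (-3.81 ± 0.31), RPL34 (-3.26) and RPL9 (-2.98). Secretory transcripts had a median of -1.14 (3 higher, 36 lower of 58, and 3 and 39 adjusted over the list alone, adjusted p = 7.23e-08), with LMAN1 at -2.58 and SSR1 at -2.43, and oxidative phosphorylation transcripts -1.19 (5 higher, 48 lower of 79, and 5 and 49 adjusted over the list alone, adjusted p = 9.02e-07), with COX7C at -2.68 ± 0.28 and UQCRFS1 at -2.02. Proteasome transcripts had -0.65 (3 higher, 14 lower of 33, the same counts adjusted over the list alone, adjusted p = 0.00767), -0.99 and -0.38 without CASC3 replicates 1 and 2, and -0.40 with the GC correction. Zinc fingers had -0.94 (44 higher, 184 lower of 393, and 45 and 189 adjusted over the list alone, adjusted p = 2.6e-05) and -0.61 with the GC correction, with ZNF276 at 3.74 ± 0.30 and ZNF292 at -3.29. Immediate early genes had -0.90 (2 higher, 14 lower of 29, and 2 and 16 adjusted over the list alone, adjusted p = 0.00609). Nuclear noncoding RNAs had -1.09 (2 higher, 5 lower of 11, the same counts adjusted over the list alone, adjusted p = 0.0461), a call lost with DESeq2 size factors (0.0524) and with the GC correction (0.304, median -0.39). These 6 lists had an adjusted p = 0.204 with an estimated correlation. Heat shock transcripts had -0.69 (12 of 22 lower, 12 adjusted over the list alone, adjusted p = 0.00215, adjusted p = 0.233 with an estimated correlation), with HSPA8 at -1.98. Translation factors had -0.72 (9 higher, 18 lower of 37, and 10 and 18 adjusted over the list alone, adjusted p = 0.0131, adjusted p = 0.405 with an estimated correlation), -0.47 with the GC correction, and did not pass without CASC3 replicate 1 (0.186).

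Single transcripts higher in CASC3 footprints than in RNA-seq included LIN7B (5.62 ± 0.79), CLASRP, a splicing regulator (5.15 ± 0.57), DMPK, the kinase gene of myotonic dystrophy (4.90 ± 0.41, adjusted p = 0.00011), SSBP4 (4.74 ± 0.60), the splicing factor ZRSR2 (4.67 ± 0.78), MRPS24 (3.90 ± 0.52) and MRPL4 (3.99 ± 0.48). LINC00324 had 2 counts in CASC3 footprints and was 384-fold higher in RNA-seq (95% counting interval 106 to 3170). HIST1H4J had 1 count and was 146-fold higher in RNA-seq (25.8 to 5780), and 72.8-fold without RNA-seq replicate 2. Lists that did not pass had medians of -0.59 for mitochondrial ribosomal proteins, 0.55 for snoRNA hosts (8 higher, 1 lower, with SNHG17 at 2.30), 0.20 for NMD targets (mean -0.02), 0.93 for EJC genes (9 higher, 2 lower), 0.75 for NMD factors and -0.30 for cell cycle genes (adjusted p from 0.05 to 0.977). CASC3 (1.31 ± 0.24) and RNPS1 (2.27 ± 0.43) were higher, RBM8A was lower (-1.24 ± 0.27), and EIF4A3 (-0.08) and MAGOH (0.32) were not called. In all 3345 transcripts were higher and 2984 lower of 12379 (edgeR), with 3839 and 3872 called without RNA-seq replicates 1 and 2.

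RNPS1 footprints were set against the same RNA-seq libraries, again without adjustment for transcript length or number of junctions. Ribosomal protein transcripts were lower with a median of -3.06 (80 of 82 lower, 0 higher, 80 adjusted over the list alone, adjusted p = 9.02e-31, adjusted p = 0.215 with an estimated correlation), among them RPL21 (-5.43 ± 0.36), RPL35A (-5.04 ± 0.30), RPL34 (-3.95) and RPS27A (-3.86). Histone transcripts had a median of -3.98 (40 of 40 lower, 40 adjusted over the list alone, adjusted p = 8.77e-25), with HIST1H2AI at -6.44 ± 0.37 and HIST1H2AG at -5.15, and small RNAs -5.89 (23 of 28 lower, 23 adjusted over the list alone, adjusted p = 1.51e-15), with RNY4 at -9.67 ± 0.92, RNY3 at -8.54 and RN7SL2 at -8.46. Detained-intron transcripts were higher, with a median of 1.79 (14 of 15 higher, 14 adjusted over the list alone, adjusted p = 6.94e-06, adjusted p = 0.142 with an estimated correlation), including CCNL2 (3.78 ± 0.37) and CLK2 (3.32 ± 0.31), as were SR and hnRNP transcripts, with 1.30 (27 higher, 5 lower of 40, the same counts adjusted over the list alone, adjusted p = 2.2e-05), including LUC7L (3.17 ± 0.31). Histones, small RNAs and SR and hnRNP transcripts had an adjusted p = 0.167 with an estimated correlation. The small RNA median was -3.31 without CASC3 replicate 1, -3.11 without RNPS1 replicate 1, and -3.12 and -3.90 without RNA-seq replicates 1 and 2.

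Secretory transcripts had a median of -1.32 (2 higher, 43 lower of 58, and 2 and 44 adjusted over the list alone, adjusted p = 5.07e-08), with the cargo receptors TMED10 at -3.70 ± 0.30 and TMED2 at -2.95, and mitochondrial ribosomal proteins -0.67 (7 higher, 32 lower of 70, and 7 and 31 adjusted over the list alone, adjusted p = 0.0298). Both had an adjusted p = 0.167 with an estimated correlation, and the latter did not pass without CASC3 replicate 2 (0.0509), RNPS1 replicate 1 (0.0532) or RNA-seq replicate 2 (0.0679). Oxidative phosphorylation transcripts had -1.49 (7 higher, 50 lower of 79, and 8 and 50 adjusted over the list alone, adjusted p = 8.55e-09, adjusted p = 0.0769 with an estimated correlation), with COX7C at -4.49 ± 0.28 and UQCRFS1 at -3.32. Translation factors had -1.11 (5 higher, 24 lower of 37, the same counts adjusted over the list alone, adjusted p = 0.000484, adjusted p = 0.283 with an estimated correlation). Heat shock transcripts had -1.16 (16 of 22 lower, 16 adjusted over the list alone, adjusted p = 0.000954, adjusted p = 0.225 with an estimated correlation), with HSPA8 at -2.19. Immediate early genes had -1.17 (1 higher, 16 lower of 29, the same counts adjusted over the list alone, adjusted p = 0.00403), and zinc fingers -0.79 (46 higher, 184 lower of 393, and 46 and 183 adjusted over the list alone, adjusted p = 8.94e-05) and -0.49 with the GC correction, with ZNF260 at -3.47. Both had an adjusted p = 0.199 with an estimated correlation.

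Single transcripts higher in RNPS1 footprints than in RNA-seq included IDUA, a lysosomal enzyme gene (4.59 ± 0.48, adjusted p = 4.6e-05), TPM2, a tropomyosin (4.46 ± 0.64), and ITIH4 (4.43 ± 0.51). FN3K had 2 RNA-seq counts and was 49.3-fold higher in footprints (95% counting interval 13.5 to 409), and 29.7-fold without RNPS1 replicate 2. LINC00324 had 0 counts in RNPS1 footprints and was at least 957-fold higher in RNA-seq, against a floor of 3 counts over the group, and MIR21, with 1 count, was 636-fold higher in RNA-seq (113 to 25200). Lists that did not pass had medians of -0.34 for the proteasome, 0.24 for snoRNA hosts, -1.38 for nuclear noncoding RNAs, -0.12 for NMD targets, 0.85 for EJC genes (7 higher, 2 lower), 0.56 for NMD factors and -0.30 for cell cycle genes (adjusted p from 0.0549 to 0.738). CASC3 was higher (1.07 ± 0.24, adjusted p = 0.0027) but did not pass without RNA-seq replicate 1 (0.0684), and RBM8A was lower (-0.97 ± 0.24, adjusted p = 0.0053) but did not pass without RNA-seq replicate 2 (0.0554) or with the GC correction (-0.52, adjusted p 0.0565). RNPS1 (0.63), EIF4A3 (-0.31) and MAGOH (-0.53) were not called. In all 3973 transcripts were higher and 3664 lower of 12379 (edgeR).

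The position of footprints within transcripts was measured as shares of exon counts, since EJCs are deposited upstream of junctions and last exons have no junction downstream. Last exons took 13.7% ± 2.5 (SD, n = 2) of counts in crosslinked CASC3 footprints and 12.3% ± 0.685 in RNPS1 footprints, against 35.3% ± 0.776 in RNA-seq, and single-exon transcripts 3.42% ± 2.11 and 2.16% ± 0.254 against 20.9% ± 2.80. For single-exon transcripts the CASC3 libraries (1.92% and 4.91%) lay on both sides of the RNPS1 libraries (1.98% and 2.34%). Internal exons took 69.6% ± 1.35, 73.6% ± 0.589 and 36.0% ± 1.67. First exons took 12.7% ± 1.79 in CASC3, 11.4% ± 0.175 in RNPS1 and 7.50% ± 0.337 in RNA-seq, and 10.8% to 18.1% in the 5 native libraries. With cycloheximide first exons took 2.16% ± 0.096 of CASC3 footprints and 11.2% ± 7.89 of RNPS1 footprints, where the libraries differed (5.66% and 16.8%), and last exons 17.6% ± 6.59 and 19.3% ± 2.11. Internal exons then took 79.1% ± 6.76 and 66.7% ± 6.32.

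In exact two-sided permutation tests of these shares the smallest p that 2 against 2 libraries allow is 0.333, so no difference could pass. The first-exon share differed by -10.54 percentage points between treated and untreated CASC3 footprints. Inside bins of exon GC content, a test chosen after the result was seen, 11.9% to 34.0% of its log2 value was left in a count-weighted mean. The last-exon share differed from RNA-seq by -21.59 points in CASC3 and -23.04 points in RNPS1 footprints. None of these groups overlapped, as chance alone gives in 33.3% of such comparisons. CASC3 and RNPS1 footprints without treatment overlapped in first exons (difference 1.26 points, exact permutation p = 0.667).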

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

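In this part the tests on exon profile, GC content and cell lines were chosen only after the result was seen. The tests on depth and on a mislabelled sample were fixed before it was seen. The thinned untreated libraries and the joint CPM of the immediate early genes were added after. The response to cycloheximide differed between CASC3 and RNPS1 footprints in 10 gene lists, by the interaction test with a preset correlation, and in none with an estimated correlation. The median difference of the responses, CASC3 minus RNPS1, was negative for ribosomal proteins (-1.77), histones (-2.60), small RNAs (-2.92), nuclear noncoding RNAs (-1.33) and zinc finger genes (-0.49). It was positive for cell cycle genes (1.52), heat shock genes (1.49), proteasome genes (1.21), SR and hnRNP genes (0.93) and secretory genes (0.66). Without treated RNPS1 replicate 1 the calls of small RNAs (median 0.83), zinc finger genes (0.16) and nuclear noncoding RNAs (-1.22) were lost.

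Ribosomal protein transcripts stood higher in CASC3 than in RNPS1 footprints without cycloheximide, with all 83 values positive, as did histones (median 0.97, 36 of 37 positive) and small RNAs (1.60, but -0.86 without crosslinked CASC3 replicate 2). The share of ribosomal protein counts in CASC3 footprints (1.86% and 4.03%) lay between RNPS1 footprints (0.741% and 0.618%) and RNA-seq (4.81% and 4.64%), as carried-over cellular RNA would also give. The median first-exon share of ribosomal protein transcripts was 12.71% and 12.95% in CASC3 footprints, above 7.88% and 8.16% in RNPS1 footprints and 5.44% and 5.10% in RNA-seq. Their last-exon share was 12.11% and 6.61% in CASC3 footprints, against 12.24% and 11.11% in RNPS1 footprints and 23.87% or more in RNA-seq. In crosslinked footprints this argues only against carried-over RNA that keeps the exon profile of RNA-seq as the whole cause for them. Carried-over RNA would also meet RNase I, and its exon profile after that was not measured, so carry-over as such stays open. Carry-over with any profile stays open for histones, for small RNAs and for the native pairs, single libraries in which first-exon shares (5.40% for CASC3 against 3.33% for RNPS1, and 6.39% against 7.90%) and last-exon shares (13.01% against 12.02%, and 11.69% against 10.42%) of ribosomal protein transcripts lay nearer RNA-seq on the CASC3 side. A GC bias as the whole cause is argued against by the GC correction, which left a median of 1.84 and 33 called members. The FLAG-CASC3 and FLAG-RNPS1 cell lines cannot be told apart from the complexes in the crosslinked samples or in the native EIF4A3 pair. In native libraries of the FLAG-MAGOH line the median was 0.27, above random lists (upper bound 0.08) but well under 1.76, and it has no replicates. Reads shared with pseudogenes and a difference between the complexes themselves stay open and untested.

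Treated RNPS1 replicate 2 correlated less with replicate 1 (r = 0.772 in log2 CPM) than with the untreated RNPS1 libraries (0.837 and 0.831) and the native libraries (0.823 to 0.850, highest with MAGOH-RNPS1). Low read depth alone is argued against. Treated CASC3 replicate 2 thinned to 467741 counts kept a correlation of 0.924 (0.923 to 0.925 in 10 draws) with its replicate. Between the treated RNPS1 replicates the correlation was 0.786 in the same measure. Thinning draws reads independently, while these counts come from PCR-amplified reads, so it cannot test for too few molecules before amplification, which stays open. A wholly untreated, mislabelled sample was examined with 16 immediate early genes called with cycloheximide in CASC3 footprints. Their median change from untreated RNPS1, less the median of all transcripts, was 1.34 in replicate 2 (14 of 16 above 0) and 0.34 in replicate 1 (12 of 16). Untreated libraries thinned to the same depth gave -0.08 to 0.37 (RNPS1), 0.08 to 0.61 (CASC3) and -0.46 to 0.54 (native). Replicate 2 lay above these ranges. Replicate 1, treated by its label, was scored at its full 7251722 counts and was not thinned, so its 0.34 cannot be set against them. Together the genes held 620 CPM in replicate 2, 461 in replicate 1, 306 and 238 in untreated RNPS1, and 672 and 625 in untreated RNA-seq. Replicate 1, the only treated RNPS1 library to compare with, had a small change that was not measured at this depth. The test therefore cannot decide whether replicate 2 was treated. The first-exon share, 16.8%, lies by native MAGOH-CASC3 and MAGOH-RNPS1 (16.5% and 18.1%) and above untreated RNPS1 (11.6% and 11.3%). The GC content was 52.8% against 48.3% in replicate 1. An untreated sample stays open, as do a partly treated sample and one mixed with untreated or native material, which were not tested. No biological explanation was tested, because the labels give these libraries the same treatment.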

How the results depend on the processing

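The GC correction, and the count ratios with 1 library left out, were chosen after seeing the data. The other settings were fixed before the data were examined. With each group at 2 libraries, a library left out leaves its group with 1, which is then assumed to vary like the others. Direction changes are counted only where 1 of the settings passed. Where neither passed, the direction differed in 49 list results and 13 gene results.

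Counts of called transcripts moved by over 1.5 times as follows, and the cause was not tested. For CASC3 against RNPS1 without cycloheximide (80) they were 265 with no filter, 266 in DESeq2, 318 with the GC correction and 612 with only these groups. With cycloheximide (2017) the count was 0 with only these groups. The same restriction raised the count without cycloheximide to 612, and that for cycloheximide in CASC3 footprints from 4551 to 6414. Fewer samples alone therefore do not explain the 0. The 2017 calls rest on a spread estimated over all crosslinked groups together. Replicates correlated at 0.971 for treated CASC3 and 0.772 for treated RNPS1. For cycloheximide in RNPS1 footprints (3) the counts were 145 with no filter, 126 in DESeq2, 1 with multi-exon transcripts, 21 with the GC correction and 0 with only these groups. For the interaction (0) they were 459, 390 and 230 with no filter, DESeq2 and the GC correction. Exons (299) gave 0 at 10 counts or more per group, where fewer exons were tested, and 935 with the GC correction, which called exon use in 1 gene. Over multi-exon transcripts first-exon shares were 11.7% (RNPS1) and 9.47% (RNA-seq), internal-exon shares 72.1% (CASC3), 75.2% (RNPS1) and 45.5% (RNA-seq), and the last-exon share of RNA-seq 44.6%. Native correlations were 0.145, 0.391 and 0.154 with a prior of 0.5 counts and 0.389, 0.672 and 0.361 at 50 counts or more. List calls were 0 in every comparison with an estimated correlation, and 9 against 5 for cycloheximide in RNPS1 footprints with the GC correction. Counts not named here stayed within 1.5 times. The GC correction also exchanged transcripts: it kept 74 of 80, 1694 of 2017, 2122 of 4551 (cycloheximide in CASC3 footprints), 3820 of 6329 and 5355 of 7637 (CASC3 and RNPS1 against RNA-seq), and transcripts without a GC value were not tested with it.

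Leaving out 1 library gave 0 to 795 transcripts for CASC3 against RNPS1 without cycloheximide, 0 to 5011 with it, 356 to 7030 and 0 to 2033 for cycloheximide in CASC3 and RNPS1 footprints, 0 to 3474 for the interaction and 3839 to 6667 for CASC3 against RNA-seq. It gave 0 to 3439 exons, exon use in 0 to 31 genes, first-exon shares of 11.3% to 11.6% in RNPS1 footprints, and 4 to 9 lists for cycloheximide in RNPS1 footprints. RNPS1 against RNA-seq gave 5423 to 8304 transcripts. The immediate early list with cycloheximide pointed down without treated RNPS1 replicate 1, with a median of 1.10 and an adjusted p of 0.962. Its median ran from 0.38 to 1.57 over the libraries left out. Shares of single libraries ran wider in some treated groups, from 5.66% to 16.8% for first exons in RNPS1 and 12.9% to 22.2% for last exons in CASC3.

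The replicate block gave 148 transcripts for CASC3 against RNPS1 without cycloheximide, 3179 with it, 7 for cycloheximide in RNPS1 footprints and 177 for the interaction, and with it the snoRNA host list did not pass for cycloheximide in RNPS1 footprints (median -0.37, adjusted p 0.0524). Differences between replicates A and B correlated at 0.035 to 0.325 between crosslinked groups and at -0.022 to 0.017 with RNA-seq, so the letters were not taken to pair samples.

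Of 220 results for named genes, DESeq2 left 195 as they were, added 24 calls and lost 1, DESeq2 size factors lost 1 (OTUB1, adjusted p 0.0502), and no filter added 23. The GC correction added 17 and lost 3 of 206, multi-exon transcripts lost 1 of 182, and only the groups compared lost 47 and added 3 of 206. Leaving out 1 library left 1333 of 1636 values as they were, lost 243 calls and added 60. Of 133 list results, DESeq2 size factors kept 131, the GC correction 121 and an estimated correlation 64, which lost 69 calls. On simulated data at the depth of these libraries 31 of 100 changes of 4-fold and 85 of 100 of 16-fold were recovered, with 8 calls among unchanged transcripts. There each transcript had the same spread in all groups. The real groups differed in spread (replicate r = 0.971 for treated CASC3 and 0.772 for treated RNPS1), so these rates may not hold for them.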

Other observations

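In this part the tests of GC content and of treatment on first-exon shares were chosen only after the result was seen. Ribosomal protein transcripts held 1.86% and 4.03% of counts in crosslinked CASC3 footprints, 0.741% and 0.618% in RNPS1 footprints and 4.81% and 4.64% in RNA-seq. With cycloheximide they held 1.18% and 0.881% in CASC3 and 0.887% and 1.55% in RNPS1 footprints. Of the 79 transcripts called higher in CASC3 footprints without treatment, 48 lay above their RNA-seq level in both CASC3 libraries and 11 did in both RNPS1 libraries. Among the 17 called ribosomal protein transcripts the counts were 5 and 0. These transcripts were chosen as higher in the same CASC3 libraries, so the larger CASC3 counts follow from the choice. Among all 83 tested ribosomal protein transcripts the counts were 7 and 0. The share over all transcripts was not counted in this way. In RNA-seq RPS12 stood at 381 and 446 CPM and MRPS24 at 28.8 and 33.8 CPM.

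In native footprints, histone transcripts had median log2 ratios of CASC3 to RNPS1 of 0.28 in the EIF4A3 pair (percentile 99.6 of random lists) and 0.06 in the MAGOH pair, and small RNAs 0.48 (percentile 99.8) and 0.02. Zinc finger transcripts had 0.03 (percentile 80.3) and 0.12 (above all random lists). With at least 50 counts in each native library their medians were 0.22 and 0.12, with 46 of 72 above 0 in each pair. MAGOH stood at 164, 170 and 84.8 CPM in the 3 native libraries of FLAG-MAGOH cells and between 28.7 and 40.6 CPM in the other native libraries. RNPS1 stood at 670 and 1360 CPM in crosslinked CASC3 footprints, 421 and 371 in RNPS1 footprints, 256 and 235 and then 200 and 633 with cycloheximide, and 250 and 222 in RNA-seq.

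First exons took a smaller share of counts in cycloheximide-treated than in untreated CASC3 footprints, 2.16% against 12.7% on average. First exons are richer in GC, with a mean of 58.9% against 49.9% for internal exons, and treated libraries were poorer in GC. Inside bins of exon GC content 11.9% to 34.0% of the log2 difference was left in a count-weighted mean, -0.28 to -0.88 of -2.31 to -2.67. The part left varied between bins. At 55% to 60% GC the log2 ratio of first to internal exon counts was -4.99 and -5.52 with treatment, against -3.88 and -3.89 without. At 70% to 75% GC it was 0.32 and -0.08 against 0.24 and 0.02. Treated RNPS1 replicate 1 stood at -3.48 at 55% to 60% GC, against -3.75 and -4.11 in untreated RNPS1 footprints. A GC bias may account for much of the pooled CASC3 difference, but not evenly over bins. It cannot be fully told apart from a shift in position, since GC and position go together. Treatment itself stays open as well: treated RNPS1 footprints stood at 5.66% and 16.8% against 11.4% on average without treatment, on both sides of it. No test here decides between library preparation and a change in where the complexes sit.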
